A study of Mus musculus with 15 samples.

How the data were processed

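RNA from the gastrocnemius of 15 male mice was labelled with biotin and hybridised to Affymetrix mouse arrays, 1 mouse per array, per the labels and the series' design text. The deposited values are log2 intensities processed with RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes. The version of RMA, the scanner, and any slide, hybridisation or scan day are not given in the sources used here, so no batch could be tested. The deposited table held 35556 probe sets on 15 arrays with no missing value. Quantiles of the arrays were close, with medians from 5.40 to 5.48, and no further normalization was applied.

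Probe sets were named from the platform annotation: 21789 had 1 gene symbol, 1621 had several and were left out, and 12146 are not listed there and are unnamed here. Of the named probe sets, 21698 matched the RefSeq table of assembly GRCm38.p6 through their Entrez identifier, and no symbol needed updating. That table was used only for names and for which genes neighbour Sirt3. The 19938 genes were each represented by the probe set with the highest mean over all arrays (999 genes had more than 1). Genes with a mean below the 40th percentile of the listed probe sets, 5.32 on the log2 scale, were removed, which left 12056. The percentile was to be taken over probe sets that are not controls. No control names occur in the table, so it was taken over the 23410 listed ones.

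Groups came from the genotype and diet in the labels. All 15 arrays were fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group (lmFit and eBayes), and 7 contrasts were taken: CR in each genotype, their difference, CR averaged over genotypes, and knockout against wildtype on each diet and averaged. Tests were two-sided with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. Errors beside log2 changes are moderated standard errors, and errors beside group means are SDs between arrays. Single values were tested by exact permutation of the arrays.

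Before the data were examined, 36 gene lists were fixed (metabolic and mitochondrial pathways, fibre type genes, stress and proteolysis, genes flanking Sirt3, and markers of other cell types), with 854 entries of which 794 matched a probe set. The 34 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and on ranks, and the flanking genes also with fry. The genes named were also fixed then: Sirt3, up to 10 genes with the largest increase and 10 with the largest decrease among those past the threshold (for pairs of groups, without overlap of the arrays; for averages, with the same direction in both strata), the 5 smallest p where under 5 genes passed, up to 4 members past the threshold in each list, and the 2 members with the smallest p of a list that shifted with none past. Other genes named were chosen after their values were seen: Prm1, Cela1, Alb and the transcripts in the closing observations.

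Alternatives fixed at the same time were no filter and a filter at the 60th percentile, the mean of a gene's probe sets, every probe set tested singly, quantile normalization, centring of each array on its median, a trended robust prior, a fit on only the groups compared, array weights, the replicate number as a block, and leaving out each array. Those added after the data were seen were leaving out the 2 arrays with the strongest germ cell transcripts, leaving out the 4 arrays on which a set of another tissue exceeded 2 log2 units over the median array, and an exact permutation test of each list's mean per array, which at this number of arrays cannot pass for a single list after adjustment over 34 lists. Camera with an estimated correlation was also added for the fits without the 2 and without the 4 arrays. The 9 tissue sets behind this were also written after the data were seen.

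The fit was tested on simulated data with 200 of 12056 genes changed. For CR in wildtype mice it recovered 94% of genes changed by 1 log2 unit and 62% of those changed by 0.5, with 9 false calls. For CR averaged over genotypes it recovered 96% and 90%, with 12 false calls, and for the interaction 86% and 26%, with 7. In these runs camera called the shifted list in every contrast and 0 of 30 unshifted lists. The simulated genes varied independently of each other, so these runs do not test the preset correlation on lists whose genes vary together. The simulated arrays also lacked the transcripts of other tissues that some real arrays carry. Recovery and false calls on the real arrays may therefore differ from these rates. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.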

Results

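Gene expression was measured in the gastrocnemius, a calf muscle made mostly of fast fibres, of male C57BL/6 mice at 12 months of age. The design crossed 2 genotypes, wildtype and knockout of Sirt3 (a mitochondrial NAD-dependent deacetylase), with 2 diets, control and calorie restriction (CR). There were 3 wildtype control, 4 wildtype CR, 4 knockout control and 4 knockout CR arrays, each from 1 mouse. Values are deposited log2 RMA intensities, and the medians of the 15 arrays over all probe sets differed by at most 0.0859. The number of arrays, 3 or 4 per group, limits the precision of every comparison. The comparisons address how CR changed muscle transcripts, whether that response differed without Sirt3, and how the genotypes differed on each diet.

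The Sirt3 transcript, represented by 1 probe set, was lower in knockout muscle on every array. Its log2 value was 6.52 ± 0.11 (SD, n = 7) in wildtype and 5.57 ± 0.49 (SD, n = 8) in knockout mice, and the lowest wildtype value, 6.38, lay above the highest knockout value, 6.19. An exact permutation test of these genotype means, without regard to diet, gave a two-sided p of 0.000622 over 6435 splits. The limma difference averaged over the diets was -0.96 (SE 0.18), or 0.514 of the wildtype signal. Some knockout values lay below the filter value of 5.32, so this ratio need not be the share of transcript left. The log2 difference was -0.93 on the control diet (exact permutation p = 0.0857) and -0.99 on CR (exact permutation p = 0.0286). Among 12056 genes in limma the averaged difference had an adjusted p of 0.318. Knockout arrays spread from 4.94 to 6.19, against 6.38 to 6.68 in wildtype. Whether the probes lie inside the deleted part of the gene is not given in the sources used here. CR left Sirt3 within the spread between arrays in both genotypes, at -0.14 (SE 0.27, limma adjusted p = 0.823) in wildtype and -0.20 (SE 0.25, limma adjusted p = 0.773) in knockout mice.

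**Figure D1:**
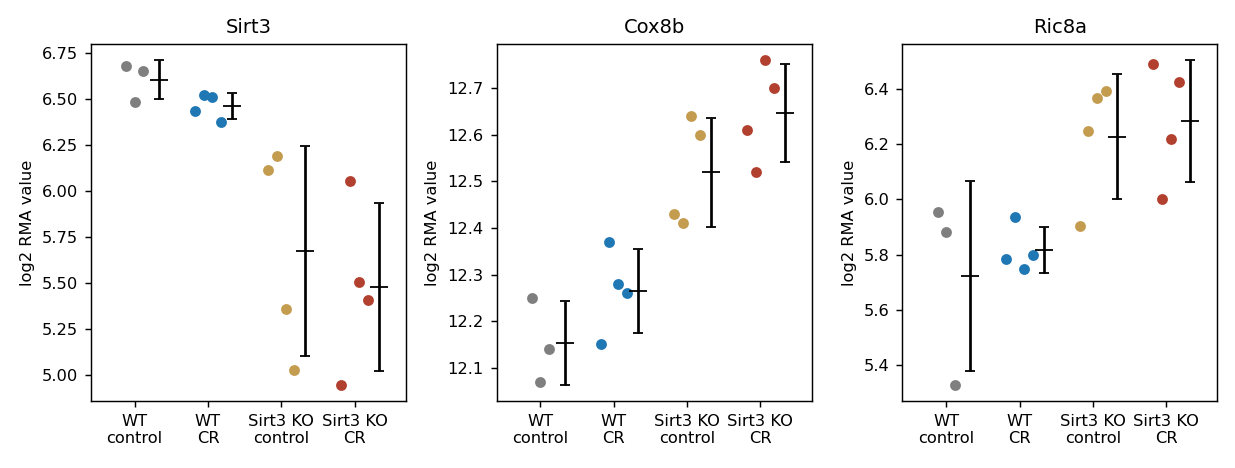
Log2 RMA values of Sirt3 and of Cox8b and Ric8a, which lie near it, on each array of the 4 groups (points), with the group mean and SD (bars). All 8 knockout arrays lie below the 7 wildtype arrays for Sirt3, with the highest knockout value at 6.19.

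Transcripts of other tissues were present on some arrays. A set of 24 male germ cell genes lay 4.01 log2 units above the median array on wildtype control replicate 3 and 3.17 above it on knockout control replicate 1, where Prm1, a sperm chromatin protein, reached 11.82 and 11.40. On the other 13 arrays the germ cell set lay at most 0.273 above. Its abundant members were graded on these: Prm1 was at 9.17 on knockout control replicate 2, 8.91 on wildtype CR replicate 3, 8.52 on wildtype control replicate 2 and 8.09 on knockout CR replicate 3, and at 6.38 to 7.25 on the other 9. A set of 9 pancreatic acinar genes lay 7.37 above on wildtype control replicate 2, where the elastase Cela1 reached 11.27. A set of 15 liver genes lay 2.82 above on wildtype CR replicate 4, where albumin (Alb) reached 11.95, and 1.31 and 1.60 above on wildtype control replicate 1 and knockout control replicate 2. So each of the 3 wildtype control arrays carried one of these sets. Counts without the 2 germ cell arrays, and without the 4 arrays on which a set exceeded 2 log2 units, stand beside each comparison.

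**Figure D2:**
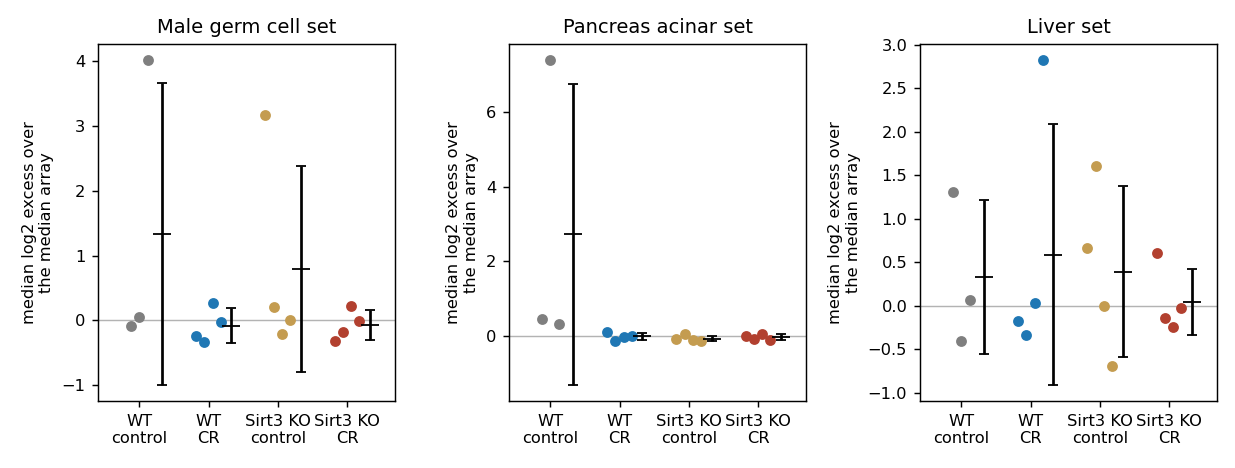
Median log2 excess of the male germ cell, pancreas acinar and liver sets over the median array, for each array (points) with the group mean and SD (bars). The germ cell set stands at 4.01 and 3.17 on 1 wildtype and 1 knockout control array, and the pancreas set at 7.37 on 1 wildtype control array.

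In wildtype mice, CR raised 13 genes and lowered 2 of 12056 tested (limma, adjusted p under 0.05). The largest increases were in 2 sarcomere genes. Mybph, a thick filament protein, went from 8.90 ± 0.28 (SD, n = 3) to 10.25 ± 0.19 (SD, n = 4), a log2 change of 1.35 (SE 0.16, limma adjusted p = 0.00546). Actc1, cardiac alpha-actin, went from 11.43 to 12.76, a change of 1.33 (SE 0.16, limma adjusted p = 0.00546). Mylpf, the fast regulatory myosin light chain, rose by 0.50 (SE 0.09, limma adjusted p = 0.0489). Misp3, Afap1l1, Mafa, Ctnnbip1, Gstm2, Dhrs7c and Stxbp4 rose by 0.47 to 0.75. Odc1, the rate-limiting enzyme of polyamine synthesis, fell by 1.08 (SE 0.18) and Slc39a10, a zinc importer, fell by 0.69 (SE 0.12), with limma adjusted p of 0.0419 and 0.0499. For each of these 12 genes all 4 CR arrays lay on the called side of all 3 control arrays, which was a condition for naming them. The count depended on the planned settings: it was 1 higher and 0 lower with only the groups compared or with the replicate number as a block. It was 4 higher and 0 lower without a filter, and 8 higher and 0 lower with quantile normalization or the mean of probe sets, so these 5 settings ended both decreases. Otherwise it was 9 and 1 with every probe set tested singly, 10 and 1 with centring, 11 and 4 with array weights, 16 and 2 with the trended prior and 21 and 2 with the 60th percentile. Among the fixed lists, 11 of 34 shifted in camera with a preset correlation. None held when the correlation was estimated, with a smallest adjusted p of 0.446. Fast fibre genes shifted up (median 0.14, 1 of 16 past the threshold over all genes and 8 higher adjusted over the list alone). Glycolysis and glycogen genes also shifted up (median 0.14, 0 of 28 past over all genes and 8 higher adjusted over the list alone). Tendon markers shifted down (median -0.52, 0 of 12 past over all genes and 5 lower adjusted over the list alone), with Tnmd at -0.79. Macrophage and leukocyte markers (median -0.25, H2-Eb1 at -0.60, 4 lower adjusted over the list alone), collagen and matrix genes (-0.14, Sparc at -0.43, 2 lower adjusted over the list alone) and fatty acid oxidation genes (-0.14, Cpt2 at -0.41, 0 adjusted over the list alone) also shifted down. Glucocorticoid response genes (0.30, Sgk1 at 0.86, 1 higher adjusted over the list alone) and proteasome genes (0.12, Psmd13 at 0.34, 5 higher and 1 lower adjusted over the list alone) shifted up, as did smooth muscle and pericyte markers (0.17) and mitochondrial ribosome genes (0.09), both with 0 adjusted over the list alone. The heat shock list shifted down with all arrays (median -0.23, 0 of 20 past over all genes, 2 lower adjusted over the list alone). Its median was 0.12 without the 4 arrays on which a set of another tissue exceeded 2 log2 units. In that fit wildtype control replicate 1, with the liver set at 1.31, is the only wildtype control array. Per array, the fast fibre, collagen, macrophage and glucocorticoid list means did not overlap between the diets (exact permutation p = 0.0286 each, adjusted p = 0.243). Those of the glycolysis and tendon lists did not overlap either (exact permutation p = 0.0571 each). The heat shock, fatty acid oxidation, proteasome, mitochondrial ribosome and smooth muscle list means overlapped (exact permutation p of 0.143 or more). In all 15 fits without 1 array, 5 of the 11 lists were called: fast fibre, glycolysis, tendon, macrophage (median -0.12 without wildtype control replicate 1) and collagen. The other 6 lost the call in at least 1 fit. At the highest camera adjusted p, fatty acid oxidation stood at -0.01 (0.196) without wildtype control replicate 1, and heat shock at -0.05 (0.101) and smooth muscle at 0.10 (0.320) without wildtype control replicate 3. Mitochondrial ribosome stood at 0.07 (0.271) without wildtype control replicate 2, proteasome at 0.10 (0.313) without wildtype CR replicate 1 and glucocorticoid response at 0.32 (0.179) without wildtype CR replicate 4. Without the 2 germ cell arrays the proteasome, smooth muscle, mitochondrial ribosome and heat shock lists lost the call, and without the 4 arrays these and the glucocorticoid and glycolysis lists. In these fits fatty acid oxidation stood at -0.24 and -0.31, macrophage markers at -0.34 and -0.58 and collagen at -0.16 and -0.09, and without the 2 arrays glycolysis stood at 0.09 and glucocorticoid response at 0.19. Slow fibre genes, not called with all arrays, stood at -0.61 (camera adjusted p = 0.0179) and -0.49 (adjusted p = 0.00862). The circadian clock list (-0.10) was also gained without the 2, and the SIRT3 substrate (-0.05) and antioxidant (-0.04) lists without the 4. With an estimated correlation the smallest camera adjusted p was 0.217 without the 2 arrays, and without the 4 only macrophage markers passed. That pass rests on wildtype control replicate 1, whose macrophage list mean was 0.446 relative to all arrays, against 0.0353 and 0.0866 on replicates 2 and 3. Without the 2 germ cell arrays 4 genes were called, 2 higher and 2 lower and 2 of them among the 15. Without the 4 arrays 8 were called, 3 higher and 5 lower and 2 among the 15, with 1 wildtype control array left and assumed to vary like the others. All 15 genes kept their direction in both fits, at an unadjusted limma p under 0.05 without the 2 arrays. Their choice on mostly the same arrays nearly fixed this in advance. Leaving out 1 array gave 41 genes without wildtype control replicate 2, 24 without wildtype control replicate 1 and 19 without knockout control replicate 1. It gave 4 to 9 without any other array, and Actc1, Misp3 and Mybph were called in all 15 such fits.

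In Sirt3 knockout mice, CR lowered 7 genes and raised 1 (limma, adjusted p under 0.05). Ankrd1, a stretch-responsive sarcomere protein, fell by 3.21 (SE 0.44, limma adjusted p = 0.0142), from 9.85 ± 0.37 (SD, n = 4) to 6.64 ± 0.83 (SD, n = 4). Hspb1, a small heat shock protein, fell by 1.47 (SE 0.18, limma adjusted p = 0.0131). Flnc, which encodes the Z-disc crosslinker filamin C, fell by 1.44 (SE 0.19), Enah, an actin regulator, fell by 1.34 (SE 0.22), and Lmcd1 fell by 1.32 (SE 0.22). The Hsp40 cochaperone Dnaja4 fell by 0.98 and the ubiquitin ligase Rnf115 fell by 0.93, while Mir409 rose by 0.41 (SE 0.07). Mir409 was dim, near the filter value of 5.32. It lay at 5.10 to 5.35 on knockout control, 5.55 to 5.67 on knockout CR and 5.11 to 5.41 on wildtype arrays. The filter used the mean over all arrays, which the knockout CR arrays raised, so the increase of Mir409 rests on signal near that limit. For all 8 genes the 4 CR arrays lay on the called side of the 4 control arrays, which was a condition for naming them. Under the planned settings the counts of higher and lower genes were 0 and 3 with quantile normalization, 0 and 4 with centring or the trended prior and 2 and 4 without a filter. They were 1 and 7 as before with the mean of probe sets or every probe set tested singly, and 0 and 12 with the 60th percentile. They were 2 and 13 with the replicate number as a block, 1 and 16 with only the groups compared and 6 and 18 with array weights. Heat shock response genes shifted down as a group, with a median of -0.53 over 20 genes, 1 lower over all genes and 17 lower adjusted over the list alone. Camera gave an adjusted p of 4.72e-22 with the preset correlation and an adjusted p of 0.0567 with an estimated correlation. The mean of the list per array was 9.32 ± 0.14 on control diet and 8.62 ± 0.06 on CR (SD, n = 4 each) without overlap, with an exact permutation p of 0.0286, the smallest this design allows, which no single list could bring past the threshold after adjustment over 34 lists. The list means of fast fibre genes (0.0788) and of denervation and immature fibre genes (-0.188) also differed without overlap, at the same exact permutation p. The latter list of 18 genes was not called in camera and includes Ankrd1, which fell by 3.21. Its mean was not taken without Ankrd1, so the difference need not describe its other genes. Of the 9 lists besides heat shock that shifted in camera, fast fibre genes (median 0.10, 6 of 16 higher adjusted over the list alone), adipocyte markers (0.48, 0 of 12) and glycolysis and glycogen genes (0.13, 4 higher and 1 lower of 28 in the same count) were up. Proteasome genes (-0.09, 3 of 32 lower adjusted over the list alone), collagen and matrix genes (-0.10, 2 of 30), tendon markers (-0.30, 1 of 12), and mitochondrial ribosome (-0.05), mitochondrial chaperone (-0.10) and macrophage (-0.20) genes, with 0 each, were down. None of these 9 held with an estimated correlation (adjusted p of 0.230 for fast fibre genes and 0.814 or more for the rest). In all 15 fits without 1 array, 3 of the 10 lists were called: heat shock, fast fibre and macrophage. The other 7 lost the call in at least 1 fit. At the highest camera adjusted p, mitochondrial ribosome stood at -0.01 (0.477) and mitochondrial chaperones at -0.05 (0.207) without knockout control replicate 3, and glycolysis at 0.09 (0.128) without knockout control replicate 1. Collagen stood at -0.05 (0.111) and tendon at -0.12 (0.111) without knockout CR replicate 4, and proteasome at -0.04 (0.0594) and adipocyte at 0.35 (0.0594) without knockout CR replicate 2. Without the 2 germ cell arrays the collagen (-0.04) and glycolysis (0.09) lists lost the call. In that fit the fatty acid oxidation (-0.19), TCA cycle (-0.09), SIRT3 substrate (-0.12), antioxidant (-0.07), OXPHOS complex I (-0.06) and OXPHOS complexes II to V (-0.07) lists passed with the preset correlation, at an adjusted p of 0.00856 or less. Mitochondrial ribosome genes stood at -0.08 and proteasome genes at -0.05. Without the 4 arrays the same 6 lists were gained, and the proteasome list was lost as well. The smallest adjusted p with an estimated correlation was 0.0541 without the 2 and 0.0607 without the 4. Without the 2 germ cell arrays 4 genes were called, all lower and among the 8, and without the 4 arrays 33 (2 higher and 31 lower), 7 of them among the 8. Leaving out 1 array gave 0 genes without knockout CR replicate 1 or 2, and 2 without knockout control replicate 2 or knockout CR replicate 4. It gave 3 without knockout control replicate 1, 4 without wildtype CR replicate 1 or 3, 5 without knockout control replicate 3 and 15 without wildtype control replicate 1.

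**Figure D3:**
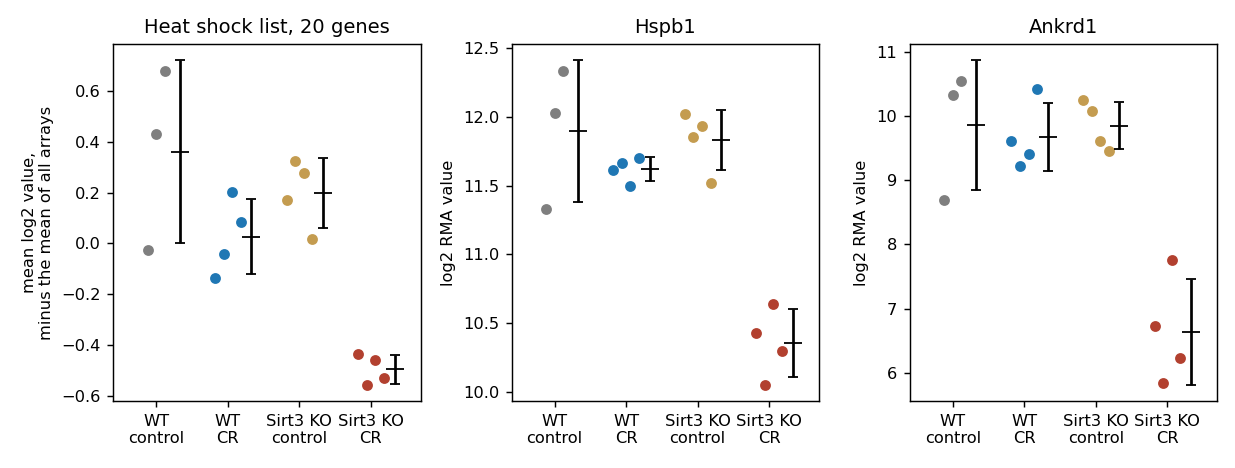
Mean log2 value of the 20 heat shock genes relative to the mean of all arrays, and log2 RMA values of Hspb1 and Ankrd1, on each array (points) with the group mean and SD (bars). The 4 knockout CR arrays lie below all other arrays in each panel, at 5.84 to 7.75 for Ankrd1.

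The difference between the CR responses of the genotypes, tested as an interaction, passed for 0 of 12056 genes in limma, with 689 genes at an unadjusted p under 0.05 where chance gives 603. Mybph had the smallest p, with a response 1.51 lower in knockout mice (log2 difference -1.51, SE 0.22, limma adjusted p = 0.0822). Its level was 8.90 in wildtype control muscle, 10.25 on CR, and 9.90 and 9.74 in knockout muscle on the control diet and CR. Ankrd1 (-3.02, SE 0.64), Hspb1 (-1.20, SE 0.27), Hspb7 (-1.19, SE 0.25) and Mlec (-0.77, SE 0.17) followed, each with a limma adjusted p of 0.641. In camera with the preset correlation, heat shock (median -0.31, 6 of 20 lower adjusted over the list alone), proteasome (-0.16, 1 of 32 lower adjusted over the list alone), mitochondrial ribosome (-0.15) and lipogenesis (-0.40) genes had a lower response in knockout mice. Fatty acid oxidation genes (0.12) had a higher one, and each of the 5 lists had an adjusted p of 1.0 when the correlation was estimated. Only the proteasome and mitochondrial ribosome lists were called in all 15 fits without 1 array. At the highest camera adjusted p, fatty acid oxidation stood at 0.01 (0.690) without knockout control replicate 1, heat shock at -0.04 (0.175) without wildtype control replicate 1 and lipogenesis at -0.24 (0.307) without wildtype CR replicate 1. Without the 2 and without the 4 arrays heat shock stood further down, at -0.38 (camera adjusted p = 6.93e-11) and -0.585. The latter fit has wildtype control replicate 1 as its only wildtype control array. Fatty acid oxidation lost the call without the 2 and lipogenesis without the 4. The OXPHOS complexes II to V (-0.07) and glucocorticoid (-0.355) lists were gained only without the 2. Macrophage markers (0.39) were gained only without the 4, on the same single wildtype control array. The smallest adjusted p with an estimated correlation was 0.394 and 0.150. For the mean of the heat shock list per array the difference was -0.36 (exact permutation p = 0.209 over 2450 relabellings of genotype within diet). This relabelling assumes no genotype difference on either diet. A genotype difference on CR, where the list means differed by -0.521, widens the relabelled values, so this p cannot decide the interaction. Over all genes the log2 changes under CR in the 2 genotypes had Pearson r = 0.518 and Spearman rho = 0.417 and the same sign for 66.3% of genes, across genes that are not independent replicates. No gene was called in both genotypes, where independent lists would share 0.00108 higher and 0.00116 lower genes. Of the calls, 13 of the 15 wildtype and 8 of the 8 knockout calls had the same sign in the other genotype. The correlation fell to 0.2 without the 2 germ cell arrays, to 0.160 without the 4 arrays, to 0.215 without wildtype control replicate 3 and to 0.235 without knockout control replicate 1. The interaction passed for 7 genes without wildtype control replicate 2, for 1 without knockout CR replicate 2 and for 6 without the 4 arrays. Of the planned settings the 60th percentile gave 1 gene and the others 0.

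Averaged over the genotypes, CR raised 78 genes and lowered 51 (limma, adjusted p under 0.05). Among the 10 largest decreases, Ankrd1 fell by 1.70, Xirp1 fell by 1.30, Hsp90aa1 (a cytosolic HSP90) fell by 1.19 and Klhl40 fell by 1.05, and Otud1 fell to 0.353 of its control level. Enah fell by 0.91, Rcan1 (a calcineurin regulator) fell by 0.90, Hspb1 fell by 0.87 (SE 0.13, limma adjusted p = 0.0127), and Flnc and the Hsp40 cochaperone Dnajb4 each fell by 0.85. In wildtype and knockout mice taken singly, the log2 differences were -0.19 and -3.21 for Ankrd1, -0.28 and -1.47 for Hspb1, -0.26 and -1.44 for Flnc and -0.84 and -0.86 for Dnajb4. The interaction had a limma adjusted p of 0.641 for Ankrd1 and Hspb1, 0.663 for Flnc and 0.994 for Dnajb4. Peg3 rose by 0.89, Ctxn3 by 0.87, Actc1 by 0.85 (SE 0.11, limma adjusted p = 0.00751), Igfbp3 (an IGF binding protein) by 0.78, Pla2g4e by 0.70, Dhrs7c by 0.56, Ccdc141 by 0.54, and Smyd2, Dusp7 and Ube4a by 0.53 each. Of the 36 named genes past the threshold, 32 had all 8 CR arrays on the same side of their own genotype's control mean, and Ankrd1, Klhl40, Otud1 and Xirp1 had 7 of 8. This was largely set by their choice on these same arrays. For the largest changes the same direction in both genotypes was a condition for naming them. In the heat shock list 5 of 20 genes fell, among them Bag3 (-0.63) and Hspa4 (-0.30), and 14 were lower adjusted over the list alone (median -0.35, adjusted p = 0.153 with an estimated correlation). In the fast fibre list 5 of 16 rose, among them Mylpf (0.38, SE 0.06), Actn3 (0.19), Myoz1 (0.18) and Tnni2 (0.18), and 9 were higher and 1 lower adjusted over the list alone (median 0.12, adjusted p = 0.162 with an estimated correlation). The glycolytic enzymes Pkm (0.24) and Tpi1 (0.21) rose, and 13 of 28 glycolysis and glycogen genes were higher and 1 lower adjusted over the list alone (adjusted p = 0.860 with an estimated correlation). In the collagen and matrix list Sparc (-0.31) fell and 13 of 30 were lower and 2 higher adjusted over the list alone (adjusted p = 0.292 with an estimated correlation). Among tendon markers Prg4 (-0.67), the joint lubricant lubricin, fell and 7 of 12 were lower adjusted over the list alone (adjusted p = 0.436 with an estimated correlation). Macrophage and leukocyte markers shifted down (median -0.22, 0 of 18 past over all genes, 10 lower adjusted over the list alone, adjusted p = 0.292 with an estimated correlation). Fatty acid oxidation genes (-0.08) shifted down and adipocyte (0.43) and smooth muscle (0.14) markers up, these 3 with an adjusted p of 0.999 with an estimated correlation. Single members of other lists also passed: Cd34 (-0.24), Gclm (-0.34), Psme4 (-0.23) and Tbc1d1 (-0.56) fell, and Taldo1 (0.29) and Tsc1 (0.25) rose.

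All 129 genes kept their direction without the 2 germ cell arrays and without the 4 arrays, which their choice on mostly the same arrays nearly fixed in advance. In the former 45 genes were called (19 higher and 26 lower), 36 of them shared, and in the latter 5 (2 higher and 3 lower), with 2 shared. The count was 23 without wildtype CR replicate 1 or knockout CR replicate 4, 27 without wildtype control replicate 3, 30 without knockout CR replicate 2 or 3, and 33 and 41 without wildtype CR replicates 2 and 3. It was 44 and 52 without knockout control replicates 3 and 2, 48 without wildtype CR replicate 4, 62 without knockout control replicate 1, 68 without wildtype control replicate 2 and 260 without wildtype control replicate 1. Of the 9 lists 6 were called in all 15 fits. For the other 3, at their highest camera adjusted p, fatty acid oxidation stood at -0.035 (0.279) without wildtype control replicate 1, adipocyte at 0.32 (0.0655) without wildtype CR replicate 1 and smooth muscle at 0.11 (0.113) without wildtype control replicate 3. Smooth muscle also lost the call without the 2 and without the 4 arrays. Without the 2 and without the 4 arrays fatty acid oxidation stood at -0.21 and -0.24 and macrophage markers at -0.28 and -0.41. Gained in both were the slow fibre (-0.385 and -0.37), SIRT3 substrate (-0.06 and -0.125), TCA cycle (-0.05 and -0.07), antioxidant (-0.03 and -0.05), OXPHOS complex I (-0.03 and -0.06) and interferon response (-0.08 and -0.06) lists, at a camera adjusted p of 0.0372 or less. The circadian clock (-0.08) was gained only without the 2, and fasting and PPAR targets (-0.09) and OXPHOS complexes II to V (-0.05) only without the 4. With an estimated correlation the smallest camera adjusted p was 0.109 without the 2, and without the 4 only macrophage markers passed. In the latter fit wildtype control replicate 1, which had the highest macrophage list mean of all arrays (0.446), is the only wildtype control array. In all 15 of these fits 20 of the 129 genes were called, among them Actc1, Dhrs7c, Igfbp3, Mylpf, Hspb1, Dnajb4 and Rcan1. Quantile normalization of the deposited values gave 59 higher and 25 lower genes in place of 78 and 51. The excess of higher genes ended with array weights (83 higher and 103 lower), without a filter (16 each) and with the replicate number as a block (18 each). It stayed with the 60th percentile (106 and 83), the mean of probe sets (78 and 52), every probe set tested singly (90 and 67), centring (88 and 69) and the trended prior (103 and 66).

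**Figure D4:**
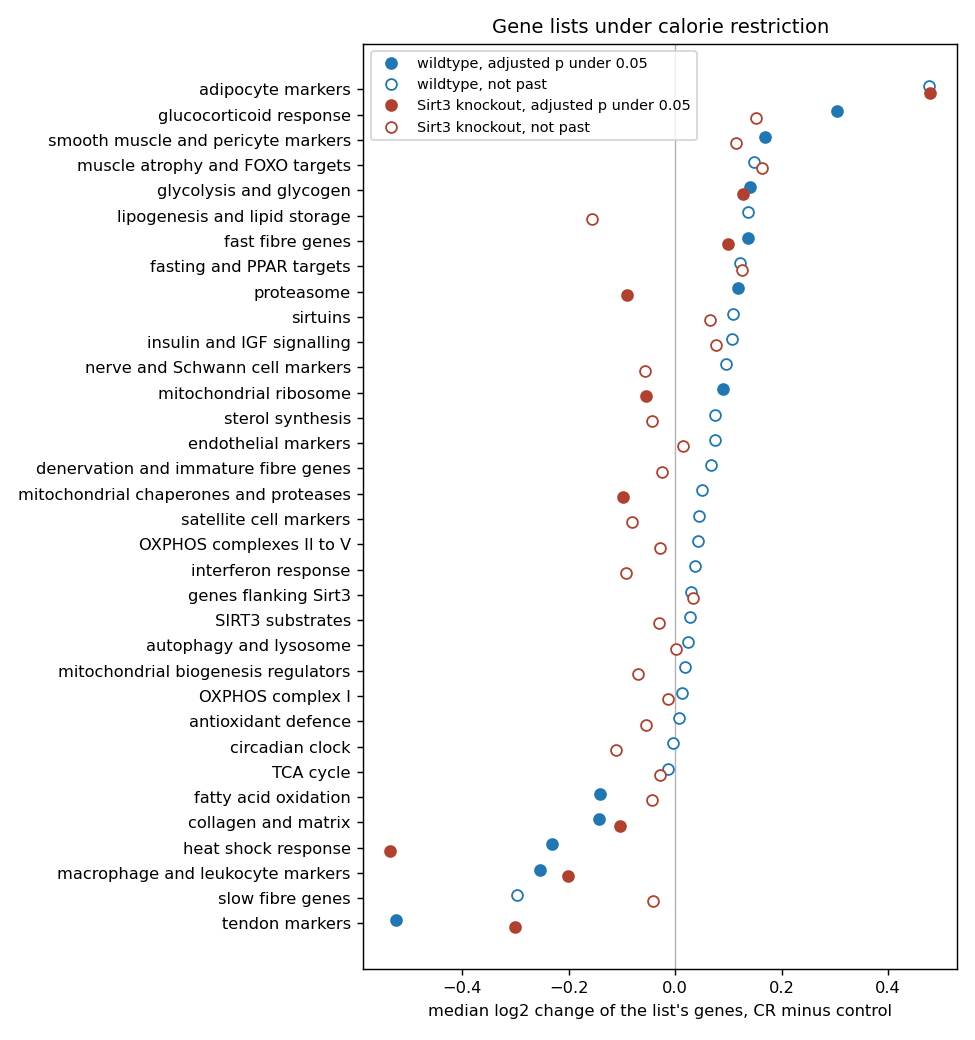
Median log2 change under CR of the genes of each of 34 lists, in wildtype (blue) and Sirt3 knockout mice (red), with filled points for lists past an adjusted p of 0.05 in camera with the preset correlation. Heat shock genes stand at -0.23 in wildtype and -0.53 in knockout mice, and with all arrays no list passed with an estimated correlation.

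On the control diet, 0 of 12056 genes differed between knockout and wildtype muscle in limma, with 847 at an unadjusted p under 0.05. Actc1 stood at 12.48 ± 0.20 (SD, n = 4) in knockout and 11.43 ± 0.27 (SD, n = 3) in wildtype muscle. Actc1 (1.05, SE 0.16) and Mybph (1.00, SE 0.16) had the smallest p, each with a limma adjusted p of 0.125. Apobec2 (0.36), Ndufaf4 (0.38) and Emc8 (0.33) followed. Fasn, the fatty acid synthase, stood at 9.68 ± 0.29 in knockout and 7.52 ± 0.23 in wildtype muscle (2.16, SE 0.62, limma adjusted p = 0.599), and Elovl6 at 8.14 and 6.22 (1.92, SE 0.63). With the preset correlation the lipogenesis (median 0.31), OXPHOS complex I (0.11, 33 of 35 positive), OXPHOS complexes II to V (0.12, 41 of 41 positive), TCA cycle (0.09), mitochondrial ribosome (0.14), sterol synthesis (0.14), proteasome (0.10) and Sirt3 flanking (0.09) lists shifted up and tendon (-0.33) and collagen (-0.02) down. With an estimated correlation each had an adjusted p of 0.739 or more. Adjusted over the list alone, 3 proteasome genes and 1 gene each of the flanking and the OXPHOS complexes II to V lists were higher, 1 tendon marker was lower, and 0 genes of the other 6 lists passed. Cox8b, which lies near Sirt3 and was 0.36 higher here, belongs to both the flanking and the OXPHOS complexes II to V lists. Their counts are therefore not independent. The lipogenesis, proteasome and tendon list means per array did not overlap between the genotypes (exact permutation p = 0.0286 each, and 0.324 after adjustment over 34 lists). The list means of OXPHOS complexes II to V overlapped (exact permutation p = 0.2). The count of genes was 0 without the 2 germ cell arrays, 5 without the 4 arrays, 11 without wildtype control replicate 2 and 1 without wildtype CR replicate 3. Of the planned settings the fit of only the groups compared gave 1 gene and the others 0. In all 15 fits without 1 array, 5 of the 10 lists were called: OXPHOS complexes II to V, mitochondrial ribosome, lipogenesis, proteasome and tendon. Without knockout control replicate 3, OXPHOS complex I stood at 0.04 (camera adjusted p = 0.237), the TCA cycle at 0.02 (adjusted p = 0.949) and OXPHOS complexes II to V, still called, at 0.05 (adjusted p = 0.0168). At the highest camera adjusted p, flanking genes stood at 0.09 (0.197) without wildtype control replicate 2, sterol synthesis at 0.09 (0.346) without knockout control replicate 1 and collagen at -0.01 (0.199) without knockout control replicate 4. The smallest median of the flanking genes was 0.048, without knockout control replicate 4. The proteasome and sterol lists lost the call without the 2 and without the 4 arrays, and the TCA cycle and flanking lists without the 4. Without the 4 OXPHOS complex I stood at 0.07, and collagen stood at -0.10 without the 2 and -0.08 without the 4. Gained in both were glucocorticoid response (0.35 and 0.31), slow fibre (-0.42 and -0.63) and macrophage (-0.12 and -0.32) genes, at a camera adjusted p of 0.0467 or less. SIRT3 substrates (0.125) were gained only without the 2, and heat shock genes only without the 4, where they stood higher in knockout muscle (0.25). In that fit replicate 1 is the only wildtype control array. Its heat shock list mean was -0.028 relative to the mean of all arrays, against 0.432 and 0.68 on wildtype control replicates 2 and 3. The smallest adjusted p with an estimated correlation was 0.585 and 0.206.

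On CR, Ankrd1 and Hspb1 were lower in knockout than in wildtype muscle (limma, adjusted p under 0.05). Ankrd1 stood at 6.64 ± 0.83 against 9.66 ± 0.53 (SD, n = 4 each), a difference of -3.03 (SE 0.44), and Hspb1 at 10.36 ± 0.25 against 11.62 ± 0.09, a difference of -1.26 (SE 0.18), both with a limma adjusted p of 0.0406. Neither gene passed without a filter, with centring, with the trended prior or with the replicate number as a block, each of which gave 0 genes. The other planned settings gave 2 genes with the mean of probe sets, 3 with the 60th percentile, every probe set tested singly or quantile normalization, 5 with only the groups compared and 7 with array weights, all lower. Flnc (-1.24, SE 0.19, limma adjusted p = 0.0538), Lmcd1 (-1.21, SE 0.22) and Cryab, the small heat shock protein alpha-B crystallin (-0.49, SE 0.09), did not pass. Over the heat shock list alone 11 of 20 genes were lower (median -0.45, adjusted p = 0.121 with an estimated correlation). The OXPHOS complex I (0.06), OXPHOS complexes II to V (0.07), fatty acid oxidation (0.12), adipocyte (0.35) and Sirt3 flanking (0.05) lists shifted up and the proteasome list (-0.06) down with the preset correlation, with an adjusted p of 0.996 each with an estimated one. Of these 6 lists, the flanking and the OXPHOS complexes II to V lists each had 1 gene higher adjusted over the list alone, and the others had 0. Cox8b, 0.38 higher on CR, belongs to both of these lists, so their counts are not independent. In all 15 fits without 1 array, 3 of the 7 lists were called: heat shock, OXPHOS complexes II to V and fatty acid oxidation (0.07 without wildtype CR replicate 4). For the others, at their highest camera adjusted p, OXPHOS complex I stood at 0.03 (0.0879) without knockout CR replicate 4 and proteasome at -0.03 (0.612) without knockout CR replicate 2. Flanking genes stood at 0.03 (0.0709) and adipocyte markers at 0.16 (0.363) without wildtype CR replicate 3. The proteasome and adipocyte lists lost the call without the 4 arrays. In that fit fatty acid oxidation stood at 0.07, and slow fibre genes were gained (-0.24, camera adjusted p = 0.0135). In camera with an estimated correlation the smallest adjusted p was 0.0764 without the 2 and 0.104 without the 4. The count was 6 without the 2 germ cell arrays and 13 without the 4 arrays, with both genes among them each time. It was 4 without knockout control replicate 1, 3 without wildtype control replicate 1, 2 without wildtype control replicate 3 or knockout CR replicate 3, and 0 without any of the other 11 arrays.

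Averaged over the diets, 0 of 12056 genes differed between the genotypes in limma, with 866 at an unadjusted p under 0.05. The smallest p belonged to Cox8b, a muscle isoform of a cytochrome c oxidase subunit and one of the genes near Sirt3 in the GRCm38.p6 annotation, which was 0.37 higher in knockout muscle (SE 0.06, limma adjusted p = 0.136). Sirt3 itself (-0.96), Atf5 (0.41, SE 0.07), Actc1 (0.58, SE 0.11) and Cd28 (-0.25, SE 0.05) followed, with a limma adjusted p of 0.318 each. Over the 34 tested flanking genes alone, Cox8b (adjusted p = 0.000383) and Ric8a (0.49, SE 0.11, adjusted p = 0.00806) were higher. In fry the list had a directional p of 0.00875 here and 0.195 for CR averaged over genotypes. Its mixed p was 0.00116 here and 0.000747 for CR, so the mixed p does not set genotype apart from diet. All 41 genes of OXPHOS complexes II to V (median 0.09) and 34 of 35 of complex I (0.08) had a higher mean in knockout muscle, across genes that are not independent replicates. The list means of complexes II to V overlapped between the genotypes. Knockout control replicate 1 had the lowest of all arrays (-0.108) and knockout control replicate 3 the highest (0.241). Their exact permutation p was 0.2 on the control diet and 0.143 on CR. Both OXPHOS lists and the TCA cycle (0.07), mitochondrial ribosome (0.07), SIRT3 substrate (0.07), lipogenesis (0.19), adipocyte (0.31), interferon response (0.09) and flanking (0.06) lists shifted up with the preset correlation, and heat shock (-0.18) and tendon (-0.27) genes down. With an estimated correlation the adjusted p was 0.408 for heat shock genes and 0.811 or more for the rest. Adjusted over the list alone, 9 of 20 heat shock genes and 1 of 12 tendon markers were lower and 1 of 41 genes of OXPHOS complexes II to V was higher, and apart from the flanking list the others had 0. The gene of OXPHOS complexes II to V was Cox8b, which is also in the flanking list. Of the 11 lists 7 were called in all 15 fits without 1 array. Among these, without knockout control replicate 3 OXPHOS complex I stood at 0.05, and without wildtype control replicate 3 heat shock stood at -0.12 and mitochondrial ribosome at 0.04. At the highest camera adjusted p, the TCA cycle stood at 0.03 (0.292) and SIRT3 substrates at 0.03 (0.306) without knockout control replicate 3, interferon response at 0.06 (0.163) without knockout CR replicate 1 and adipocyte at 0.22 (0.122) without wildtype CR replicate 3. These 4 also lost the call without the 4 arrays, and interferon response without the 2. Without the 4 heat shock stood at -0.11 and mitochondrial ribosome at 0.04. Gained in both fits were slow fibre (-0.25 and -0.49), glucocorticoid response (0.15 in each) and collagen (-0.05 and -0.07) genes, at a camera adjusted p of 0.0479 or less. Fatty acid oxidation (0.10) and circadian clock (-0.10) genes were gained only without the 2, and macrophage markers (-0.12) only without the 4. The smallest adjusted p with an estimated correlation was 0.168 and 0.587. The count was 7 without wildtype control replicate 1, 6 without wildtype control replicate 2, 1 without the 4 arrays and 0 without any other single array or without the 2 germ cell arrays. Of the planned settings the trended prior gave 1 gene and the others 0.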

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

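The tissue sets and all tests of the 3 patterns weighed here were chosen after the result was seen, and the counts over other splits of the arrays were planned before those counts were seen. For the spread of Sirt3, correlations across the 8 knockout arrays were run first and, after their results were seen, replaced by the tests given here because the values fall into clusters. This left the explanation by a wildtype allele open where the first tests had favoured it.

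Transcripts of male germ cells stood 4.01 and 3.17 log2 units above the median array on wildtype control replicate 3 and knockout control replicate 1, which lay apart from its group (gap over range 0.879). The excess of the 24 genes correlated between these arrays at r = 0.952 across genes, which are not independent replicates, and Prm2 reached 12.34 and 11.86 there (12 of the 24 genes also passed the muscle filter). A poorer scale of these arrays is argued against by the brain, kidney and heart sets, which rose by at most 0.0591 on them, and the control diet or a genotype by the other 5 control arrays, where the germ cell set reached at most 0.204. Weaker signal was seen on 1 array of each group: Prm1 was at 8.09 to 9.17 on wildtype control replicate 2, wildtype CR replicate 3, knockout control replicate 2 and knockout CR replicate 3, against 6.38 to 7.25 on the other 9. RNA from testis in these samples may be the source. On wildtype control replicate 3 and knockout control replicate 1 a Leydig and Sertoli cell set stood at 0.727 and 0.288, far less than the germ cell set. A seminal vesicle and epididymis set stood at -0.149 and -0.12 there. How such RNA entered was not tested.

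Sirt3 spread from 4.94 to 6.19 over the 8 knockout arrays, with no array between 5.50 and 6.05, so no correlation across them is given. A swap between the genotypes is argued against by a gap of 0.185 between the highest knockout and the lowest wildtype array. Testis or liver RNA may add signal on knockout control replicates 1 and 2, but knockout CR replicate 2, at 6.05, had both sets at or below the median array (higher of them -0.144), so this cannot be told for all of the spread. A remaining wildtype allele or wildtype RNA also stays open: knockout control replicates 1 and 2 and knockout CR replicate 2, with the most Sirt3, had Cox8b at 12.41 to 12.52 against 12.60 to 12.76 on the other 5, though above all wildtype arrays (by at least 0.0344), and for Ric8a 1 of 8, knockout control replicate 1, lay inside the wildtype range. No biological explanation was tested.

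Heat shock genes were lowest in restricted knockout mice. A smaller share of slow fibres is argued against, since the difference between restricted and control knockout arrays in the list mean, -0.693 (SE 0.133), was -0.712 (SE 0.135) with the slow fibre mean in the model. Germ cell RNA on 2 control arrays is also argued against, with a median of -0.575 without them. A shared dissection, hybridisation or scan day stays open, since 0 arrays have a day or slide in the labels, and could produce such a group of stress genes. Diet and genotype together also stay open: the interaction of the list mean had an exact permutation p of 0.209. That relabelling assumes no genotype difference on either diet, so it cannot decide this.

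Other splits of the arrays gave the following counts. For CR in wildtype mice 1 of 35 splits, the real one, gave 15 genes or more, and the highest other gave 4. For CR in knockout mice 1 of 35 gave 8 or more (highest other 1), for CR averaged over genotypes 1 of 100 drawn gave 129 or more (highest other 0), and for the genotypes on CR 1 of 35 gave 2 or more (highest other 1). Here the real split alone reached its count, the smallest share that 35 or 100 splits allow. A difference between the groups also widens the spread in the other splits, which lowers their counts. So these counts do not exclude a chance division of the arrays, and for the genotypes on CR they rest on 2 genes against 1. Where no gene passed, genes were counted at an unadjusted p under 0.05, and other splits reached the real count: 28 of 100 splits reached 689 for the interaction (highest other 1957), 16 of 35 reached 847 for the genotypes on the control diet (highest other 2788), and 23 of 100 reached 866 for the genotypes averaged over diets (highest other 1795). The split with 2788 genes put wildtype control replicates 2 and 3 and knockout control replicate 1, the arrays with pancreas or germ cell transcripts, against the other 4 control arrays, which points to a structure of the samples other than genotype.

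Single arrays stood apart in groups of 4 for 15 of 240 values examined, where chance gives about 12. The gap over the range was 0.830 for Mybph, 0.863 for Cd34 and 0.922 for the heart set on wildtype CR replicate 3, and 0.880 for Tbc1d1 and 0.885 for the liver set on wildtype CR replicate 4. It was 0.908 for Lmcd1 and 0.871 for Sparc on knockout control replicate 1, and 0.907 for Actn3 on knockout control replicate 4. In knockout CR mice it was 0.848 for Ctnnbip1 and 0.870 for Pkm on replicate 1, 0.882 for Mybph on replicate 2, 0.908 for Tpi1 and 0.905 for the seminal vesicle set on replicate 3, and 0.843 for Tbc1d1 on replicate 4.

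The response to CR differed between genotypes for 5 lists in camera with the preset correlation, with adjusted p of 1.02e-05 for heat shock, 8.37e-07 for proteasome, 5.47e-05 for mitochondrial ribosome, 0.0121 for fatty acid oxidation and 0.0493 for lipogenesis, and of 1.0 with an estimated correlation. Among 5466 probe sets without a single gene symbol, which the comparisons do not use, 65 differed under CR in knockout mice (7 higher) and 1 differed in the interaction, against 0 in the other 5 contrasts. The search of these probe sets was widened from CR averaged over genotypes to all contrasts after the first result was seen.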

How the results depend on the processing

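Leaving out the 2 germ cell arrays, leaving out the 4 arrays on which a set of another tissue exceeded 2 log2 units, and the exact permutation test of list means were chosen after the data were seen. The cause of a changed count was not tested, except that fewer arrays or groups in a fit leave fewer degrees of freedom. The genotype difference in Sirt3 kept its direction in all 22 settings run, with a limma adjusted p above 0.05 in each, from -1.09 without the 4 arrays to -0.85 without knockout control replicate 4. Signal near background limits dim genes, which the filter removes.

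For CR in wildtype mice 15 genes became 4 without a filter, 23 with the 60th percentile, 8 with the mean of probe sets, 8 with quantile normalization, 1 with only the groups compared, 4 (2 higher and 2 lower) without the 2 and 8 (3 higher and 5 lower) without the 4 arrays, and 4 to 41 without 1 array. For CR in knockout mice 8 became 3 with quantile normalization, 4 with centring, 4 with the trended prior, 17 with only the groups compared, 24 with array weights, 4 without the 2 and 33 without the 4 arrays, and 0 to 15 without 1 array. For the interaction 0 became 1 with the 60th percentile, 6 without the 4 arrays, and 0 to 7 without 1 array. For CR averaged over genotypes 129 (78 higher and 51 lower) became 32 (16 each) without a filter, 84 (59 higher and 25 lower) with quantile normalization, 45 (19 higher and 26 lower) without the 2 and 5 (2 higher and 3 lower) without the 4 arrays, and 23 to 260 without 1 array. For the genotypes on the control diet 0 became 1 with only the groups compared, 5 without the 4 arrays, and 0 to 11 without 1 array. For the genotypes on CR 2 became 0 without a filter, with centring or with the trended prior, 5 with only the groups compared, 7 with array weights, 6 without the 2 and 13 without the 4 arrays, and 0 to 4 without 1 array. For the genotypes averaged over diets 0 became 1 with the trended prior and 1 without the 4 arrays, and 0 to 7 without 1 array.

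The correlation of the CR effects between genotypes, 0.518, was 0.329 with array weights, 0.2 without the 2 and 0.160 without the 4 arrays, and 0.215 to 0.596 without 1 array. The replicate numbers do not pair the arrays: deviations of 21 same-numbered pairs correlated at -0.636 to 0.503 (median 0.0105, 7 over 0.1), and 2 of 15 arrays correlated best with their own number. With the replicate number as a block the counts were 1 for CR in wildtype mice, 15 in knockout mice, 36 averaged, 0 for the genotypes on CR, and 0 as before for the other contrasts.

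The difference between the genotypes in the Sirt3 response, -0.05, reversed to 0.0747 without the 2 and 0.145 without the 4 arrays, and lay between -0.267 and 0.127 without 1 array, never past the threshold. The heat shock list in wildtype mice reversed to 0.12 without the 4 arrays, a fit with 1 wildtype control array. The TCA cycle list on the control diet, between 0.0176 and 0.144 without 1 array, reversed in its test without knockout control replicate 3. Of 63 list shifts called, all lost the call with an estimated correlation, 3 on ranks, 14 with quantile normalization and 11 without the 2 arrays. Without the 4 arrays 20 lost it with the direction kept, and the wildtype heat shock list lost it with the direction reversed. Lists not called with all arrays were gained as well, without the 2 and without the 4 arrays: 2 and 3 for CR in wildtype mice, 6 and 6 in knockout mice, 2 and 1 for the interaction, 7 and 8 for CR averaged, 4 and 4 for the genotypes on the control diet, 0 and 1 on CR, and 5 and 4 averaged over diets. With an estimated correlation in these fits, chosen after the data were seen, macrophage markers passed without the 4 arrays for CR in wildtype mice and CR averaged, and no other list passed. That fit has wildtype control replicate 1 as its only wildtype control array. Its macrophage list mean was 0.446 relative to the mean of all arrays, against 0.0353 and 0.0866 on wildtype control replicates 2 and 3. The exact permutation test of list means cannot pass for a single list after adjustment at this number of arrays, so it is not counted. Without 1 array, the call was lost in at least 1 fit by 6 of 11 lists for CR in wildtype mice, 7 of 10 in knockout mice, 3 of 5 for the interaction, 3 of 9 for CR averaged, 5 of 10 for the genotypes on the control diet, 4 of 7 on CR and 4 of 11 averaged over diets. Of the named gene values, 4189 kept their side of the threshold, 689 lost the call, 37 gained it and 6, all of the Sirt3 response, reversed. No scaling moved the median of all genes by over 0.1.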

Other observations

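The values here were chosen after the data were seen. The lipogenic transcripts Fasn and Elovl6 had a wider range in the CR than in the control groups. Fasn spanned 7.43 to 10.83 over wildtype CR and 8.38 to 10.80 over knockout CR arrays, against 7.35 to 7.77 in wildtype control and 9.35 to 9.98 in knockout control muscle, and Elovl6 spanned 6.21 to 9.43, 6.67 to 9.07, 5.92 to 6.67 and 7.88 to 8.47 in the same groups. Within the wildtype CR group the adipocyte list mean lay between -0.65 on replicate 3 and 0.77 on replicate 1, relative to the mean of all arrays. Knockout control replicate 1 stood low for fasting-responsive transcripts: Pdk4, a kinase that restrains pyruvate oxidation, was at 8.89 there and at 11.95 to 12.73 on the other 14 arrays, and Ucp3 was at 6.43 against 8.77 or more.

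On the 4 knockout CR arrays 83 of 12056 genes lay below every other array, where chance gives 8.83, and 49 lay above. The 83 include 11 of the 20 heat shock genes. Every other fixed list had at most 1 gene among the 83, and each list had at most 1 among the 49. On the 3 wildtype control arrays 165 genes lay below and 51 above all others, where chance gives 26.5 each way.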
